A study of Mus musculus with 6 samples.

How the data were processed

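RNA sequencing libraries from the myocardium of male wild-type mice were compared between PBS and STZ injection, with 3 libraries per group. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected and fragmented, and the second cDNA strand was marked with dUTP. The deposited values are FPKM per gene, rounded to 2 decimals, per the file headers and the values themselves. Per the submitters' processing notes, the authors used cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d with the genome build GRCm38. The strand setting, the annotation release and the filters are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies could therefore be shared. Sept2 and Atp6v0c-ps2 are named as uncertain for this reason, but they are not the only such genes. Nppa overlaps a gene on the opposite strand over 61.5% of its exon length, Bnip3 over 22.3%, Txnip over 19.4% and Bdh1 over 13.7%. FPKM are relative to each library's total, so a large change in abundant genes moves the values of all others. Mitochondrial genes made up 42.0% to 47.3% of that total, and 7 nuclear pseudogene copies of them a further 18.9% to 20.6%. Since counts were not used, the depth could only be estimated roughly and no counting interval is given.

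The file of PBS replicate 3 stops after 7711 of 55401 genes. By a rule set before the data were examined, a library that lists fewer than 50% of the genes is left out of the comparison over all genes, which was made on PBS replicates 1 and 2 and on 3 STZ libraries. That file listed 4811 of the 11556 tested genes (41.6%). Identifiers were matched to symbols, positions, exon lengths and GC content from GENCODE release M21 of the same build, and 55141 of the 55401 identifiers had a symbol and 260 did not. Where a symbol had more than 1 identifier, the one with the highest mean FPKM was used for gene lists.

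Genes with at least 1 FPKM in at least 2 of the fitted libraries were tested on log2(FPKM + 1), a pseudocount of 1, with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All adjusted p-values for genes are from that test. No covariate was used, since the labels give no batch. Gene lists, 47 in number, were fixed before the data were examined, and 38 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over the lists tested, and again with an estimated correlation and with fry. Counts adjusted over the list alone use the same gene p-values adjusted within the list. The genes named are, by a rule set before the data were examined, the 10 largest rises and the 10 largest falls among genes past the threshold with groups that do not overlap and a mean of at least 1 FPKM in the higher group, leaving out genes named only by a clone or model identifier and immunoglobulin, T cell receptor and haemoglobin genes. To these were added up to 4 members with the smallest p of each list, and Ddx3y, Uty, Eif2s3y, Kdm5d, Xist, Myh6 and Tnnt2 as a check of the labels. Some of the genes this rule takes are not reported here. Of the genes left out by name, 71 passed the threshold. Other list members are named where they passed, to say which genes a count holds, and a few that did not pass are given as values chosen after they were seen.

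The gene test was tested on simulated data with the per-gene spread of the real libraries, over 11556 genes. It recovered 65% of 100 genes changed by 1 and 100% of 100 genes changed by 2 on the log2 scale, 6.2% of its calls were false, and it called 1 gene where none was changed. The simulated noise was normal, independent between genes and equal in both groups. Changes were placed only in genes with a higher mean FPKM than the filter asks. These rates may therefore not hold for the real libraries. The list test called 10 of 10 lists shifted by 0.5 and 0 of 17 others, with independent genes. With an estimated correlation it called 9 of the 10 shifted lists. Alternatives changed 1 choice at a time, except that the fit on the genes of all 6 files both adds the third PBS library and tests fewer genes: pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, centring, quantile normalization, TPM and rescaling without mitochondrial and haemoglobin genes, robust eBayes and no trend, the replicate number as a block, a log2 change of at least 1, a threshold of 0.1, each library left out, the third PBS library added, the genes of all 6 files and array weights. Added after the data were seen were nuclear protein-coding genes alone, rescaling without mitochondrial genes and their nuclear copies, and removal of a length and GC trend with mgcv 1.9.3. Intervals of list medians come from 400000 bootstrap draws over members, and cover the choice of members and not the spread between libraries. The R package data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 read the files, and figures were drawn with matplotlib 3.10.9.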

Results

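Gene expression was measured by RNA sequencing in the myocardium of male wild-type mice that had been injected with PBS or with STZ. STZ (streptozotocin) is a toxin of the insulin-producing beta cells of the pancreas, and the series used it to make mice diabetic. The design asked which genes differ in the diabetic myocardium. There were 3 libraries per group, all with a time label of 8 weeks, and the labels do not say from which event the time runs. They also do not say that the libraries came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. The values were FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments). They summed to between 531384 and 589719 per library in the 5 complete files. The number of fragments was not given in the sources used here and FPKM does not state it. It could only be estimated roughly from the values, so the depth behind each value is uncertain. The file of PBS replicate 3 listed 7711 of the 55401 genes (13.9%), the first part of the same identifier order. PBS replicates 1 and 2 and the 3 STZ libraries were therefore compared over all genes, and the third PBS library was set beside them where its file listed a gene.

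The Y-linked genes Ddx3y and Eif2s3y were expressed in the PBS libraries at 9.71 ± 0.714 and 10.1 ± 0.346 FPKM (SD, n = 2) and in the STZ libraries at 8.03 ± 1.58 and 10.4 ± 0.327 FPKM (SD, n = 3). Xist, expressed from the inactive X chromosome of females, lay between 0.02 and 0.07 FPKM in the 5 complete libraries. The cardiac genes Myh6 and Tnnt2 were at 3004 ± 112 and 713 ± 60.2 FPKM in the PBS libraries (SD, n = 2).

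STZ hearts expressed far more of the slow myosin heavy chain Myh7 and the lipase inhibitor Angptl4 than PBS hearts, and far less of the ketone-using enzyme Bdh1, the apelin receptor Aplnr and the fibrillar collagen Col3a1. Myh7 (ENSMUSG00000053093, chromosome 14, 54970684 to 54994626, GRCm38) went from 82.2 ± 1.11 FPKM in PBS (SD, n = 2) to 1088 ± 235 FPKM in STZ (SD, n = 3), a log2 fold change of 3.69 ± 0.20 (SE, limma adjusted p = 0.00169). Bdh1 (ENSMUSG00000046598, chromosome 16, 31422280 to 31458901) fell from 28.6 ± 4.96 to 2.06 ± 1.13 FPKM, a log2 fold change of -3.33. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) fell from 18.3 ± 1.52 to 2.03 ± 0.389 FPKM, with 14.7 FPKM in the third PBS library.

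Of 11556 genes tested with limma, 672 passed an adjusted p of 0.05, of which 421 were higher and 251 lower in STZ hearts. Among them, 172 of the higher and 114 of the lower genes changed by at least 1 on the log2(FPKM + 1) scale, which understates the change of low genes. The PBS and STZ libraries did not overlap for any of the 672 genes. Over all tested genes 47.4% had groups that did not overlap, where chance gives 20%. The higher genes made up 62.6% of the calls with FPKM as deposited, 48.5% after centring each library on its median, 50.2% after quantile normalization and 73.8% after rescaling to TPM. The count fell with fewer libraries, to 24 genes without PBS replicate 1 and 29 without PBS replicate 2, and to 348, 392 and 398 without STZ replicate 1, 2 and 3. With PBS replicate 3 added where its file listed a gene, 1169 genes passed, 667 of the 672 among them. Of the 1169, 597 were listed in that file. It listed 247 of the 672 genes, and 242 of these still passed. The remaining genes gained no value from that library, so their passing again does not test them. With no filter on low values 81 of 26229 genes passed.

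Other genes with large rises were the xenobiotic-metabolising enzyme Cyp1a1 (log2 fold change 3.16), the neutrophil calcium-binding proteins S100a9 (2.78) and S100a8 (2.52), the neutrophil gene Retnlg (2.63), the proteoglycan Spock2 (2.58), the acyl-CoA thioesterase Acot1 (2.54) and the methyltransferase Inmt (2.46). Cyp1a1 went from 1.67 ± 0.191 to 22.9 ± 2.90 FPKM (limma adjusted p = 0.00127). Aplnr fell from 10.3 ± 0.148 to 0.58 ± 0.0529 FPKM (limma adjusted p = 0.00127). The collagen Col15a1 fell by 2.46, the carboxypeptidase family member Cpxm2 by 2.50 and skeletal muscle actin (Acta1) by 2.35 on the log2 scale. The mitochondrial transfer RNA gene mt-Ti fell by 2.54, although a transfer RNA is short and carries no long poly(A) tail. Sept2 (-3.05) and Atp6v0c-ps2 (-3.33) are uncertain, because this Sept2 gene lies wholly within another annotated Sept2 gene on the same strand and Atp6v0c-ps2 is a processed pseudogene that shares sequence with its parent. Passing the threshold was a condition for the 20 genes taken by size of change. Without PBS replicate 1 or without PBS replicate 2, 18 of the 20 kept their sign, but some of them no longer passed. Aplnr and Cpxm2 were not tested there, since they then reached 1 FPKM in only 1 library.

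**Figure D1:**
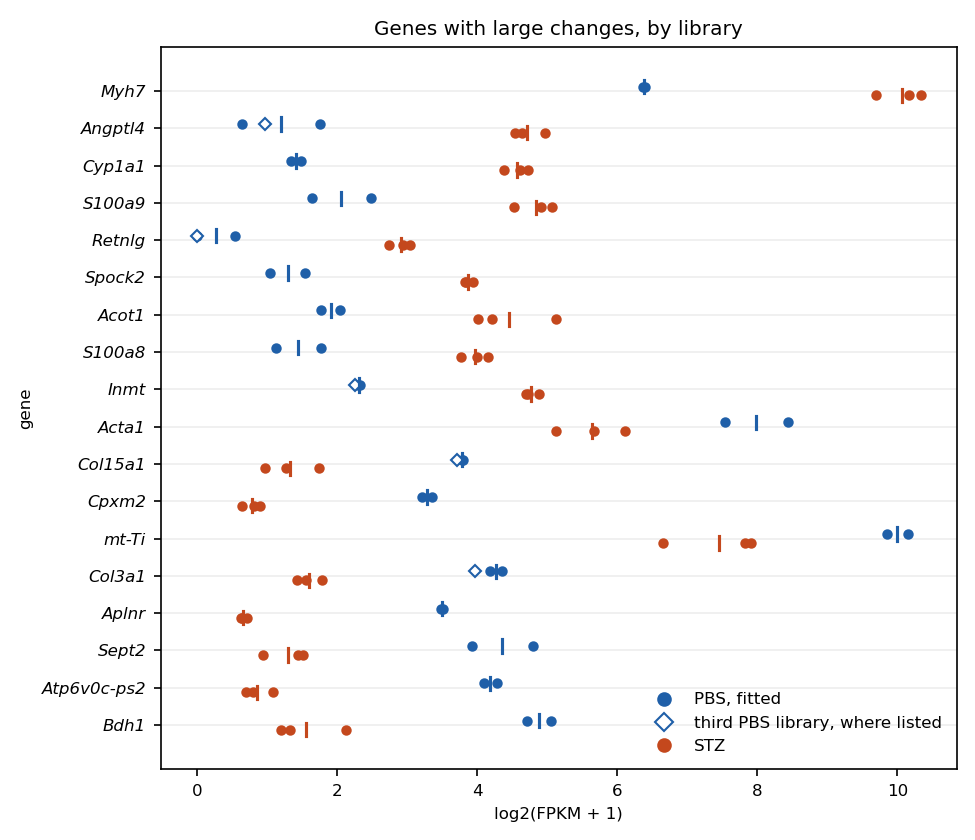
Expression of 18 of the 20 genes with the largest changes, as log2(FPKM + 1) on the horizontal axis, 1 point per library, with PBS libraries in blue, STZ libraries in orange, open diamonds for the third PBS library where its file listed the gene, and vertical bars at the mean of the fitted libraries of a group. The groups do not overlap for any of these genes, and Myh7, with a log2 fold change of 3.69, has the widest gap between the means among those drawn.

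Of 18 measured members of the list of lipid-handling genes that respond to PPAR nuclear receptors, 13 rose and 0 fell, with a median log2 fold change of 1.23 (camera adjusted p = 5.63e-10, and adjusted p = 0.442 with an estimated correlation). Pdk4, which restrains pyruvate oxidation, went from 95.6 to 541 FPKM, the mitochondrial carrier Ucp3 from 7.92 to 45.1 FPKM and the thioesterase Acot2 from 22.5 to 84.4 FPKM. Adjusted over the list alone, 15 rose. Of 24 fatty acid oxidation enzymes 7 rose, among them Acadl, Decr1 and Cpt1b, and 10 adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.000751, and adjusted p = 0.442 with an estimated correlation).

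In the list of glucose uptake and glycolysis, 4 of 21 members fell and 0 rose, and 6 fell adjusted over the list alone, while 10 of the 21 had a positive sign. They were hexokinase 2 (Hk2, 46.8 ± 1.41 to 17.1 ± 0.76 FPKM), muscle enolase (Eno3), Pfkfb2 and the insulin-regulated glucose transporter Slc2a4 (97.0 ± 0.417 to 66.3 ± 1.57 FPKM). The list's median was -0.22 (camera adjusted p = 0.01, and adjusted p = 0.442 with an estimated correlation), and without STZ replicate 1 the median was 0.0005. All 15 enzymes of branched-chain amino acid breakdown had a negative sign, with a median of -0.44 (camera adjusted p = 6.52e-07, and adjusted p = 0.202 with an estimated correlation). Ivd and Bckdhb passed alone, and 8 adjusted over the list alone. Ugp2 fell in the list of 12 glycogen genes (3 adjusted over the list alone, median -0.26, camera adjusted p = 0.00637, and adjusted p = 0.547 with an estimated correlation). Bdh1 fell among the 6 genes of ketone body metabolism, and the list did not pass (camera adjusted p = 0.39).

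Of 28 measured collagen and matrix genes 9 fell in STZ hearts and 2 rose, with a median log2 fold change of -0.62 (camera adjusted p = 1.92e-08, and adjusted p = 0.442 with an estimated correlation). Adjusted over the list alone, 16 fell and 2 rose. Col1a1 went from 13.0 ± 2.50 to 3.38 ± 0.384 FPKM, and Col6a3, Col6a2 and Col5a3 also fell. Thbs2, a matricellular protein, rose from 2 ± 0.0849 to 8.85 ± 0.583 FPKM, and the collagen cross-linking enzyme Lox rose from 0.795 to 2.95 FPKM. In the basement membrane list Col4a1 and Col4a2 fell and 0 of 13 rose (3 fell adjusted over the list alone, median -0.17, camera adjusted p = 0.0136, and adjusted p = 0.442 with an estimated correlation).

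Fibroblast markers moved both ways. Of 24 members 6 fell (Col3a1, Col1a1, Pi16, Col1a2, Smoc2 and Cd248) and Ly6c1 rose, and the list passed with a median of -0.25 (camera adjusted p = 0.00717, and adjusted p = 0.442 with an estimated correlation). Adjusted over the list alone, 10 fell and 6 rose. The fibroblast receptor Pdgfra (log2 fold change 0.37) and Tcf21 (0.25) did not pass. Of 14 markers of activated fibroblasts Meox1, Acta2 and Postn fell and 0 rose (4 fell adjusted over the list alone, median -0.41, camera adjusted p = 0.000104, and adjusted p = 0.442 with an estimated correlation). Acta2 also marks smooth muscle, and the list of 13 pericyte and smooth muscle markers, where it fell alone, did not pass (camera adjusted p = 0.24). With genes limited to those of at least 5 FPKM, the fibroblast and basement membrane lists did not pass.

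All 36 cytosolic ribosomal protein genes had a positive sign in STZ hearts, and 14 rose. Rpl3 went from 32.0 ± 0.728 to 85.2 ± 6.40 FPKM and Rplp0 from 258 ± 0.141 to 438 ± 31.9 FPKM. The list's median was 0.61 (camera adjusted p = 5.11e-15), and 36 rose adjusted over the list alone. Its members moved together within groups (estimated correlation 0.705). The list did not pass in camera with an estimated correlation (adjusted p = 0.442), a setting that raised p for lists of low correlation too. The share of mitochondrial genes in the FPKM total was 47.3% and 47.1% in the PBS libraries and 45.5%, 42.0% and 43.3% in the STZ libraries. None of the 13 mitochondrially encoded protein genes passed, and 3 fell adjusted over the list alone. Their list had a median of -0.19 (camera adjusted p = 0.01, and adjusted p = 0.574 with an estimated correlation), and it did not pass after quantile normalization or without STZ replicate 2. Of 42 nuclear-encoded respiratory chain subunits Cox7a1 fell (1138 ± 107 to 584 ± 84.9 FPKM), and neither this list (camera adjusted p = 0.0569) nor the tricarboxylic acid cycle (camera adjusted p = 0.136) passed.

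Of 18 clock genes 3 rose and 1 fell, and 6 had a negative sign. Per2 went from 0.73 ± 0.0283 to 7.63 ± 2.63 FPKM, Hlf was also among those that rose, and Arntl, the activator of the clock, fell from 2.95 ± 0.622 to 0.55 ± 0.329 FPKM. The clock list had a median of 0.76 (camera adjusted p = 0.038, and adjusted p = 0.442 with an estimated correlation), with 9 rising and 1 falling adjusted over the list alone. The list did not pass without STZ replicate 1. Of 16 glucocorticoid-responsive genes 6 rose (Fkbp5, Angptl4, Mt1, Lcn2, Map3k6 and Mt2) and 13 adjusted over the list alone, with a median of 0.95 (camera adjusted p = 6.52e-07, and adjusted p = 0.202 with an estimated correlation). In the list of insulin signalling and FoxO targets Txnip (61.4 ± 2.13 to 250 ± 31.4 FPKM), Bnip3 and Igf1r rose among 20 members (5 adjusted over the list alone, median 0.58, camera adjusted p = 0.0108, and adjusted p = 0.49 with an estimated correlation). It did not pass without STZ replicate 1.

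**Figure D2:**
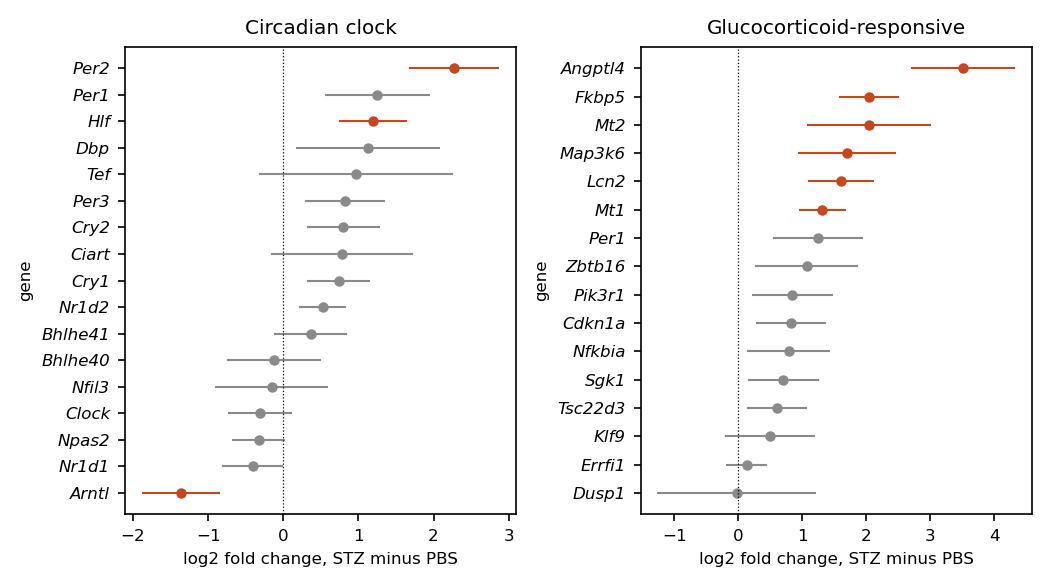
Log2 fold change of clock genes (left) and glucocorticoid-responsive genes (right) on the horizontal axis, STZ minus PBS on the log2(FPKM + 1) scale, with 95% intervals from limma as lines and genes past the threshold in orange, for 17 of the 18 clock genes. Arntl, at -1.36, lies opposite to Per2, at 2.28, and 15 of the 16 glucocorticoid-responsive genes lie above 0.

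In the list of hypertrophy and fetal genes Myh7 rose while Acta1, Mybpc2 and Rcan1 fell, and the list did not pass (camera adjusted p = 0.154), its median (-0.39) and mean (0.01) differing in sign. Myh7 made up 2.66% ± 0.06 of the FPKM of Myh6 and Myh7 in PBS (SD, n = 2) and 31.6% ± 4.91 in STZ (SD, n = 3). Nppa did not pass (624 ± 527 against 1777 ± 1010 FPKM, limma adjusted p = 0.184). Its values were 996 and 251 FPKM in PBS replicates 1 and 2, and 2864, 876 and 1591 FPKM in STZ replicates 1, 2 and 3. The atrial myosin Myl7 varied within both groups, with 262, 37.9 and 0.21 FPKM in PBS replicates 1, 2 and 3 and 357, 73.7 and 0.28 FPKM in the STZ replicates of the same numbers. Sln and Myl4 were likewise highest in replicate 1 of both groups. The fit kept STZ replicate 3, where Myl7 was near 0, and left out PBS replicate 3, where it was near 0 too. These atrial markers were therefore not balanced between the fitted groups. STZ replicate 3 had more Nppa (1591 FPKM) than PBS replicates 1 and 2, whose Myl7 was higher. Whether atrial content explains the spread of Nppa was not tested. The atrial list did not pass (camera adjusted p = 0.578). Of 24 genes of calcium handling and ion channels the pacemaker channels Hcn2 and Hcn4 and the potassium channel Kcnd2 fell (5 adjusted over the list alone, median -0.42, camera adjusted p = 0.000675, and adjusted p = 0.442 with an estimated correlation), and the list did not pass with genes of at least 5 FPKM. Actc1 and Ckm fell among 18 sarcomere genes, whose list did not pass (camera adjusted p = 0.0735). Hsph1 fell among 14 heat shock genes (2 adjusted over the list alone, median -0.40, camera adjusted p = 0.000669, and adjusted p = 0.442 with an estimated correlation).

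The list of endothelial markers passed upward, with a median of 0.40 (camera adjusted p = 0.01, and adjusted p = 0.599 with an estimated correlation). The lipid-handling genes Fabp4 and Gpihbp1 and the capillary gene Cd300lg rose and the water channel Aqp1 fell among 19 members, and 9 rose and 1 fell adjusted over the list alone. Of 13 listed neutrophil markers 3 were tested (S100a8, S100a9 and Retnlg), too few for a list test, and all 3 rose. Retnlg, at 0 and 0.46 FPKM in PBS replicates 1 and 2, met the filter only through its STZ values. The other listed markers were not tested, so the rise cannot be read as one of the whole list. Lgals3 rose among 13 macrophage markers (camera adjusted p = 0.24). In the list of antigen presentation the class II genes H2-Eb1, H2-Aa and H2-Ab1 fell and the class I gene H2-K1 rose (camera adjusted p = 0.39). Of 38 lists tested, 17 passed with the preset correlation of camera, 7 upward and 10 downward, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. That loss does not come from correlation alone. For branched-chain amino acid breakdown and glucocorticoid-responsive genes the estimated correlations (-0.016 and -0.003) lay below the preset 0.01. Their unadjusted camera p still rose, from 8.59e-08 to 0.0106 and from 7.25e-08 to 0.0103. By fry, which asks whether a list's own genes moved one way, 12 passed, 11 of them among the 17. Of the 17, the glycogen, mitochondrially encoded, and calcium handling and ion channel lists did not pass by fry. Neither did the insulin signalling and FoxO, heat shock and endothelial lists.

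**Figure D3:**
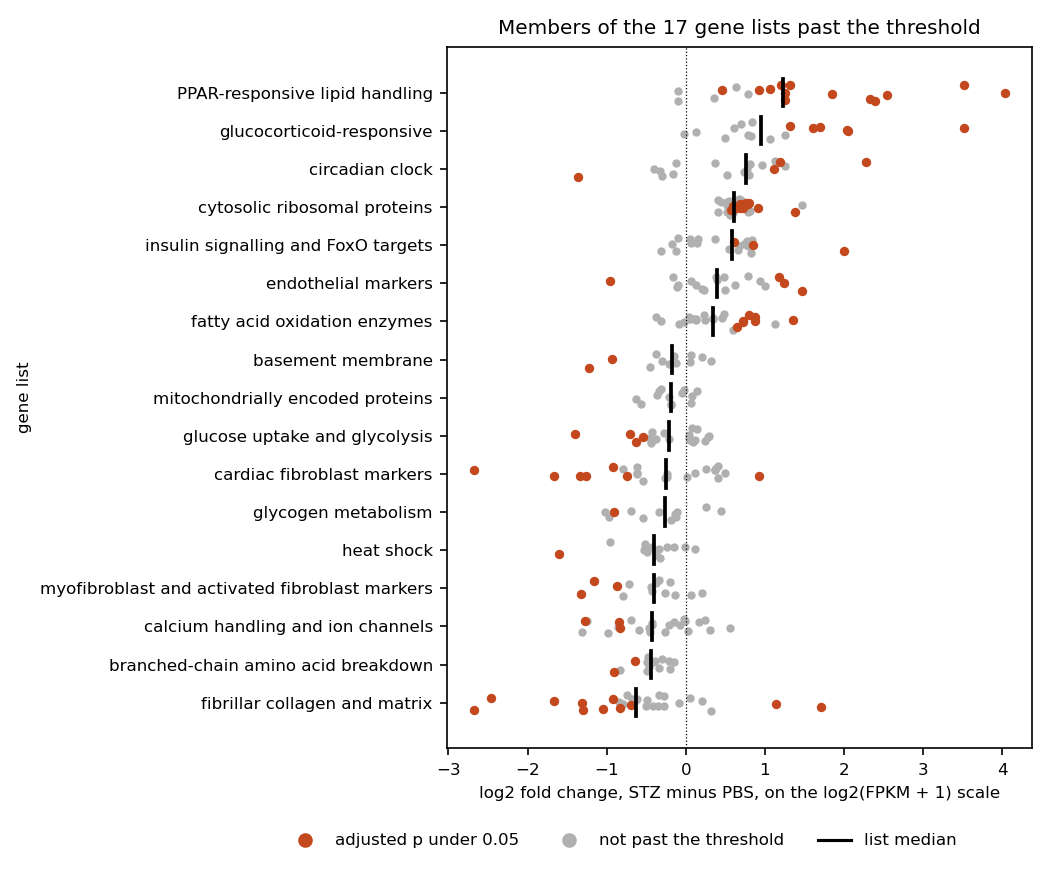
Log2 fold change of each member of the 17 gene lists that passed camera, STZ minus PBS on the log2(FPKM + 1) scale, 1 point per gene, with genes past the threshold in orange and the list median as a black bar. The medians run from -0.62 for collagen and matrix genes to 1.23 for lipid-handling genes that respond to PPAR.

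The remaining lists tested did not pass in the comparison as reported. Mt1, Hmox1, Nqo1, Ucp2 and Mt2 rose among 20 genes of oxidative stress (camera adjusted p = 0.0643), and the chaperone Hspa5, Manf and Pdia4 fell among 20 genes of endoplasmic reticulum stress (camera adjusted p = 0.0643). Maff and Myc rose among the immediate early genes (camera adjusted p = 0.0546). Ltbp4 fell in the TGF-beta list (camera adjusted p = 0.794). Scd4 and Srebf1 rose in the list of cholesterol and fatty acid synthesis (camera adjusted p = 0.793), whose median (-0.03) and mean (0.21) differ in sign. With genes of at least 5 FPKM, 6 of its 14 genes were tested, its median was 0.56 and it passed (camera adjusted p = 0.0226). Bnip3 and Sqstm1 rose in the autophagy list (camera adjusted p = 0.793), Fas in the apoptosis list (camera adjusted p = 0.154), Lcn2 in the cytokine list (camera adjusted p = 0.122), and Hmox1 and Alox12 rose while Alox5 fell in the ferroptosis list (camera adjusted p = 0.525). No member passed in the interferon list (camera adjusted p = 0.908), whose median (0.10) and test differ in sign, in the lymphatic list (camera adjusted p = 0.832), whose median (-0.06) and mean (0.04) differ in sign, or in the erythroid and platelet list (camera adjusted p = 0.578). The other 8 lists with too few measured members were those of cell cycle, T and NK cells, B cells, adipocytes, Schwann cells, mesothelium, skeletal muscle and cartilage. In these, Lipe and Cnmd rose and Aldh1a2, Acta1 and Myl1 fell.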

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

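The alternatives added after the data were seen were nuclear protein-coding genes alone, rescaling without mitochondrial genes and their nuclear copies, and the length and GC correction. The count of 672 genes moved by over 1.5 times under 6 choices besides leaving out a library. It was 81 with no filter on low values, where 26229 genes were tested, 64 with the replicate block, 286 with a log2 change of at least 1, 1642 at an adjusted p of 0.1, 1169 with the third PBS library added and 1239 with array weights. The fit on the 4811 genes of all 6 files called 986, a number near 672 but from fewer genes tested. Among the genes that the third PBS file lists, the comparison as reported called 247. Leaving out each library in turn gave 24 to 398 genes and 16 to 22 lists. With 1 PBS library left, it was assumed to vary like the STZ libraries. Leaving out PBS replicate 3 is the comparison as reported. The count of 17 lists was 0 with an estimated correlation, and 12 to 22 under the others. Among the 17, the mitochondrially encoded list was lost under the most settings, some of which leave out mitochondrial genes by construction. The median of glucose uptake and glycolysis turned to 0.0005 without STZ replicate 1 (camera adjusted p = 0.0127), the others left out giving down to -0.2832, and that of cholesterol and fatty acid synthesis to 0.5557 with genes of at least 5 FPKM (camera adjusted p = 0.0226); fewer genes were tested there, and beyond that the cause was not tested, as for the other changes. Over the 4811 genes in all 6 files the replicate numbers did not meet the rule for pairs: deviations from the group means correlated at 0.176, -0.05 and 0.15 for the same numbers, and not every library correlated best with its own number. Over these genes the block gave 752 calls against 986. Myl7, Sln and Myl4 differed with the number alike in both groups where listed. With the replicate block Nppa passed (log2 change 1.66, adjusted p = 0.0314), the hypertrophy and fetal gene programme had 2 higher genes in place of 1, and the median of the atrial cardiomyocyte markers was 0.42 in place of -0.38, with 1 higher gene (adjusted p = 0.0548). With PBS replicate 3 left out, STZ replicate 3 has no partner in its block, so this block fit compares replicates 1 and 2 alone. The fit without STZ replicate 3 makes the same comparison. Its atrial median of 0.42 (camera adjusted p = 0.529) is therefore no separate evidence. Of the values of single genes and lists under alternatives, 3978 kept their side of the threshold, 461 lost it, 221 gained it and 38 moved. Robust eBayes and the log2 change threshold were not run for lists, to which they do not apply here. The uncertain depth limits what can be said of genes near 1 FPKM.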

Other observations

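The 7 gene groups in the next 2 paragraphs were put together after their values were seen, so their counts describe these libraries and test nothing. The tests of glucocorticoid-responsive genes and of fibroblast markers were also chosen after the result was seen. Enzymes of xenobiotic oxidation and conjugation were higher in STZ hearts, 12 of 19 past the threshold and 0 lower, with a median log2 fold change of 1.00. Fmo2 went from 4.07 to 20.4 FPKM, Sult1a1 from 10.6 to 47.7 FPKM and Ephx1 from 12.3 to 30.4 FPKM, beside Cyp1a1 and Inmt. Among those that did not pass were Tiparp (2.28 against 2.44 FPKM) and Cyp1b1 (1.07 against 4.49 FPKM, limma adjusted p = 0.0882). The peptide apelin (Apln) fell with its receptor Aplnr, from 5.67 to 0.69 FPKM. The cold-inducible RNA-binding proteins Cirbp (7.29 to 32.2 FPKM) and Rbm3 (7.01 to 20.2 FPKM) both rose.

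Of 14 genes of collagen folding and hydroxylation, Serpinh1, P4ha1 and Plod1 fell and Fkbp10 and P3h4 rose. The collagen chaperone Serpinh1 went from 94.0 to 30.4 FPKM. In the serine and one-carbon group, Mthfd2, Psat1 and Phgdh rose among 5 genes, each from under 1 FPKM in PBS. Of 21 mitochondrial transfer RNA genes 11 fell, with a median of -1.20, and the ribosomal RNA mt-Rnr2 fell from 3735 to 1563 FPKM. These RNAs are short or lack long poly(A) tails, so their values in poly(A)-selected libraries depend on the selection.

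Several clock genes shifted between groups. Per1, Per2, Per3, Dbp, Tef, Hlf, Nr1d1, Nr1d2, Ciart and Bhlhe41, which peak near each other, had a median of 0.89, and the 4 genes that peak opposite to them, Arntl, Clock, Npas2 and Nfil3, a median of -0.3155 (bootstrap interval -1.36 to -0.16). Opposite signs are consistent with hearts collected at another time of day or with a shifted clock phase, though 4 genes are few, Arntl alone of them passed, and Nr1d1 (-0.41) went against its arm. A glucocorticoid response is another candidate explanation, since the 15 responsive genes outside the clock list had a median of 0.8429 (interval 0.61 to 1.70). Some of these are also in the PPAR, FoxO, oxidative stress or cytokine lists. The 8 in none of these or the clock list had a median of 0.65 (interval 0.13 to 1.70). Collection times are not in the labels, so neither was separated from the other or from an effect of diabetes.

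The collagen and matrix list was lower in STZ hearts. The tables argue against a transcript length or GC trend as the whole cause, since their median was -0.6403 (interval -0.81 to -0.36) after that trend was removed, against -0.62 before, but the trend was small (SD 0.0571 over other genes). Whether the sampled tissue held fewer fibroblasts cannot be told apart from lower expression per cell: the 20 fibroblast markers outside the matrix lists had 10 positive and 10 negative signs, and their median lay 0.5166 above that of the matrix genes with an interval of -0.005 to 1.03 that includes 0. That bound is close to 0, and of 12 shorter bootstrap runs of 10000 draws 2 put it above 0 and 10 did not. A change of fibroblast state stays open. The list of activated fibroblast markers was lower, with a median of -0.41 (camera adjusted p = 0.000104, and adjusted p = 0.442 with an estimated correlation). That list cannot tell a change of state from fewer fibroblasts, and the 2 were not tested against each other.

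Ribosomal protein genes were higher in STZ hearts. Their median was 0.5785 (interval 0.54 to 0.67) after the length and GC trend was removed, and 0.5316 (interval 0.50 to 0.61) after rescaling without mitochondrial genes and their nuclear copies, so neither that trend nor the fall in the mitochondrial share accounts for the whole rise. Both corrections were small beside the rise. The trend had an SD of 0.0569 over other genes, and the rescaling moved the median of all tested genes from 0.0607 to 0.0048. Neither could have removed a rise of this size, so the 2 results say little about its cause. Ribosomal protein pseudogenes, which share sequence with the ribosomal protein genes, had a median of 0.47 over 107 genes. The members moved together within groups, so a difference between these few libraries that is not due to STZ may remain. The list did not pass with an estimated correlation, and no list passed at that setting. In simulated data with independent genes the same setting called 9 of 10 lists shifted by 0.5. Its loss here therefore cannot be set aside as a setting that calls nothing.

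The 672 calls were set against other splits of the 5 complete libraries into 2 and 3. The real split was the 1 of 10 that gave as many, and the highest of the others gave 2 genes. With 10 splits no share under 0.05 can be reached. Every other split also mixes PBS and STZ libraries within a group. The difference between them then adds to the spread within that group, whatever its cause. Few calls in those splits therefore do not tell an effect of STZ from another difference between the libraries.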
